A study of Mus musculus with 28 samples.

How the data were processed

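The samples were H3K27me3 ChIP-seq and input libraries of sorted mouse microglia: 28 libraries, 14 of H3K27me3 and 14 of input. Per the labels, basal microglia (5 H3K27me3 libraries) came from mice on a regular diet and the CD229-CD11c-, CD229+CD11c- and CD229+CD11c+ subsets (3 H3K27me3 libraries each) from mice on 0.2% cuprizone for 4 weeks; read lengths were 100 for 4 libraries and 150 for 24. Neither an accession of a paper nor an abstract was used. Per the submitters' processing notes, Bowtie2 2.3.4.1, fastp 0.20.0, STAR 2.7.0f, HOMER and DESeq2 were used, with the builds mm10 and GRCm38; the notes do not say which step each tool served for these files.

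Per the file headers, the authors called basal regions with HOMER's replicate peak caller on basal H3K27me3 replicates 1 and 2 against 2 inputs, in mm10, with DESeq2, a size of 1250, L 0, F 2, an adjusted p of 0.05 and a log2 fold of 1, normalised to library totals. The header totals were 51756561 and 51214148 tags for the H3K27me3 libraries and 38528016 and 4788629 for the inputs. The deposited region list holds 26325 regions. Its score column in the BED file is 1 throughout per the file's values, and the authors' peak score in the annotated table runs from 8.64 to 19862.1 on a scale that is not stated. The deposited table also gives the region size in bp (the other unit), 4 per-sample columns of log2 variance-stabilised values, the log2 fold change of target over input, and the p-value columns of the authors' DESeq2 test (p_value, not altered). These served to describe the basal regions. The log2 fold over input also set the deciles of basal enrichment and was a predictor of the loess offsets described below. The region size and the basal H3K27me3 columns gave the tag density, the other predictor. The peak score column of the deposited tables of the 12 later libraries is another placeholder, 0 throughout, and was not used. The deposited table of raw counts gives tag counts per region, not normalised, for 12 H3K27me3 libraries over 26326 regions, the basal list and 1 added region at Bhlhe40, which lies within a 109 kb region of the list, so that its tags are counted in both. The other deposited table holds the authors' normalized signal, each library's counts scaled to a common total over the regions, with log2 fold changes of the second-named over the first-named group and each p-value and adjusted p-value of the authors' differential test. Those 12 signal columns served only for comparison. The inputs of the 12 libraries have no columns in the tables of counts, and no genome-wide totals of these libraries were given in the sources used here, so the share of each library's tags in the regions was not analysed here and input was not subtracted. The 2 basal libraries used to call the regions have no columns of raw counts and stayed out of the comparisons.

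Regions were tested with edgeR 4.0.16 in R 4.3.3 on the raw counts: filterByExpr, which removed 0 regions, TMM scaling over the regions, robust dispersion, and quasi-likelihood F-tests with all 4 groups in 1 model and group as the only term. P-values were adjusted by Benjamini and Hochberg over the regions of each of the 7 comparisons, and a region counted as called at an adjusted p under 0.05. Log2 CPM used a prior count of 2. Libraries held 7740002 to 11362168 tags in the regions, with a median count per region between 151 and 222. The groups, comparisons, tests, gene lists and most alternatives were fixed before the data were examined; the few chosen later are named as such.

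The rule for named regions was also fixed then. For CD229-CD11c- against basal, CD229+CD11c+ against basal and CD229+CD11c+ against CD229-CD11c- it took the 10 regions with the largest fold change each way that passed the test, had at least the median level, showed all libraries of one group above all of the other (10% of splits do so by chance for 3 against 3) and lay nearest to a named gene, 1 region per gene. For the other comparisons it took the first 3 each way; where none passed it took the 5 with the smallest unadjusted p. It added the genes of the sort panel, and the 4 members with the smallest p of each list that passed or had at least 3 called regions. Regions outside it are said to be chosen after their values were seen. Named regions with opposite signs against basal microglia in the subsets compared, and a difference that passed, were followed in that comparison too.

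The 20 gene lists were written from general knowledge: Hox clusters, other developmental transcription factors, homeostatic and disease-associated microglia, interferon response, cytokine and NF-kappa-B, antigen presentation, SLAM family, lipid handling, growth factors, pattern recognition, cell cycle inhibitors, Polycomb and H3K27 demethylases, peripheral macrophages, lymphocytes, neutrophils and dendritic cells, oligodendrocyte lineage, astrocytes, neurons, and endothelial and mural cells. A list's regions were those nearest to a member, by the deposited annotation, with their centre within 10 kb of its TSS. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and with fry beside it, adjusted over the lists of a comparison. The regions of a list all lie near a TSS, whereas camera set them against all other regions. A list can therefore pass through a change common to regions near a TSS. The Hox, homeostatic (2 regions), SLAM (0 regions) and pattern recognition (4 regions) lists had fewer than 5 regions and got no test; genes' spans in the reference annotation served for overlaps. Pattern recognition genes were overlapped by 9 regions, with a median log2 fold change of 0.05 in CD229+CD11c- and 0.00 in CD229+CD11c+ against basal microglia. Shares of regions with a TSS within 5 kb were compared by Fisher's exact test, two-sided. That test treats regions as independent, though all come from the same libraries. Its intervals and p-values therefore do not measure the spread between libraries. Shares of tags per library were compared by exact permutation.

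Alternatives were DESeq2 1.42.0, its size factors, total counts over the regions as scaling, at least 30 counts in at least 3 libraries, no filter, a non-robust dispersion, at least 2-fold as a second condition, only the 2 groups compared, each library left out in turn, and the PE150 tag of the titles as a covariate (2 tagged and 1 untagged library in every group; its meaning is not given in the sources used here). A block by the series of barcode numbers and a block by replicate number within cuprizone samples were further ones. Deviations from the group means were correlated between libraries with the same number. The values were 0.28, 0.13 and 0.46 between CD229+CD11c- and CD229-CD11c-, and 0.24, 0.13 and 0.42 between CD229+CD11c+ and CD229-CD11c- microglia. Between CD229+CD11c+ and CD229+CD11c- microglia they were 0.2, 0.08 and 0.33. The blocked counts of these comparisons are therefore given too. For the lists the alternatives were regions within 50 kb and 1 region per gene. Loess offsets on basal enrichment, and on enrichment and tag density (span 0.3), the tagged libraries alone and gene spans were added after the data were seen. Every split of 3 against 3 (10) and 100 drawn splits for the mean of the subsets were refitted. The test was tested on simulated data with the observed depth and spread: of 100 regions each changed by 1.5-fold and 2-fold, it recovered 61% and 96%, with 14 false calls among 26326 regions. A simulated trend with enrichment gave 5213 calls with TMM and 0 with either set of loess offsets. Enrichment is a predictor of both sets, so the 0 shows only that they remove such a trend. It cannot show whether they also remove a real change that follows enrichment. The slope of the trend was set and not fitted to the data, so the 5213 cannot be compared with the real counts. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.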

Results

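H3K27me3, the histone mark that Polycomb repressive complex 2 leaves at silenced genes, was profiled by ChIP-seq in microglia sorted from the brains of adult male C57BL/6 wild-type mice. Basal microglia came from mice on a regular diet. The other microglia came from mice given a diet with 0.2% cuprizone, a toxin that kills oligodendrocytes and strips myelin, for 4 weeks. They were sorted into 3 subsets by CD229, a SLAM family receptor encoded by Ly9, and CD11c, an integrin encoded by Itgax: CD229-CD11c-, CD229+CD11c- and CD229+CD11c+. The series held 28 libraries, 14 of H3K27me3 and 14 of input DNA. Counts per region were deposited for 12 H3K27me3 libraries, 3 in each of the 4 groups, with basal replicates 3, 4 and 5 as the basal group. The tags per library in the regions numbered 9742663 to 11175711 in basal microglia and 7740002 to 9982607 in CD229-CD11c- microglia. They numbered 9031448 to 10986803 in CD229+CD11c- and 8934801 to 11362168 in CD229+CD11c+ microglia. Per the labels, brains of 2 to 6 mice were pooled per condition, and nothing states that replicates came from separate animals, so the p-values measure the spread between these samples. Fold changes are log2 values ± SE from n = 3 libraries per group, and levels are counts scaled to a common library total (CPM, with TMM factors), given as means ± SD over n = 3 libraries.

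In basal microglia the mark lay over the Hox clusters and other developmental regulators, and no called region overlapped the genes of microglial identity that were tested. The 26325 regions called by the authors covered 276.8 Mb of the mm10 genome, with a median length of 6386 bp and a median log2 enrichment over input of 1.49. Of these regions, 58.8% were intergenic and 32.8% intronic, and 19.2% had a transcription start site (TSS) within 5 kb. There were 100 regions of at least 100 kb, and the 4 Hox clusters, which set body position in the embryo, were each covered by 1 broad region. The longest region of all, 410 kb at chromosome 15, 102741093 to 103151419, held 9 Hoxc genes; those over the Hoxb, Hoxd and Hoxa clusters measured 272, 198 and 156 kb. The region at Pax2, a developmental regulator, reached 217 kb. None of the 40 homeostatic microglia genes and none of the 12 SLAM family genes was overlapped by a region. Among the genes of the sort panel (Ly9, Itgax, Cd44, Ptprc, Itgam and Ace), none was the nearest gene of any region. The Ace gene was overlapped by 2 regions, which did not pass in CD229+CD11c+ against basal microglia, with fold changes of -0.23 ± 0.09 (adjusted p = 0.11) and -0.08 ± 0.07 (adjusted p = 0.55).

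The strongest basal regions took a larger share of the tags in both CD229+ subsets. The top decile of regions by basal enrichment held 16.3 ± 0.75% of the tags in regions in basal, 16.8 ± 0.26% in CD229-CD11c-, 20.1 ± 0.12% in CD229+CD11c- and 18.2 ± 0.12% in CD229+CD11c+ microglia. The differences from basal were 3.79 points for CD229+CD11c- and 1.94 points for CD229+CD11c+ microglia, each with p = 0.1 in a two-sided exact permutation test, the smallest p that 3 libraries against 3 allow. For CD229-CD11c- microglia the difference from basal was 0.52 points (exact p = 0.4). Across deciles of basal enrichment, the median fold change of CD229+CD11c- against basal microglia ran from -0.09 in the lowest to 0.21 in the highest. The same range was -0.05 to 0.17 in CD229+CD11c+ and -0.01 to 0.05 in CD229-CD11c- microglia.

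**Figure D1:**
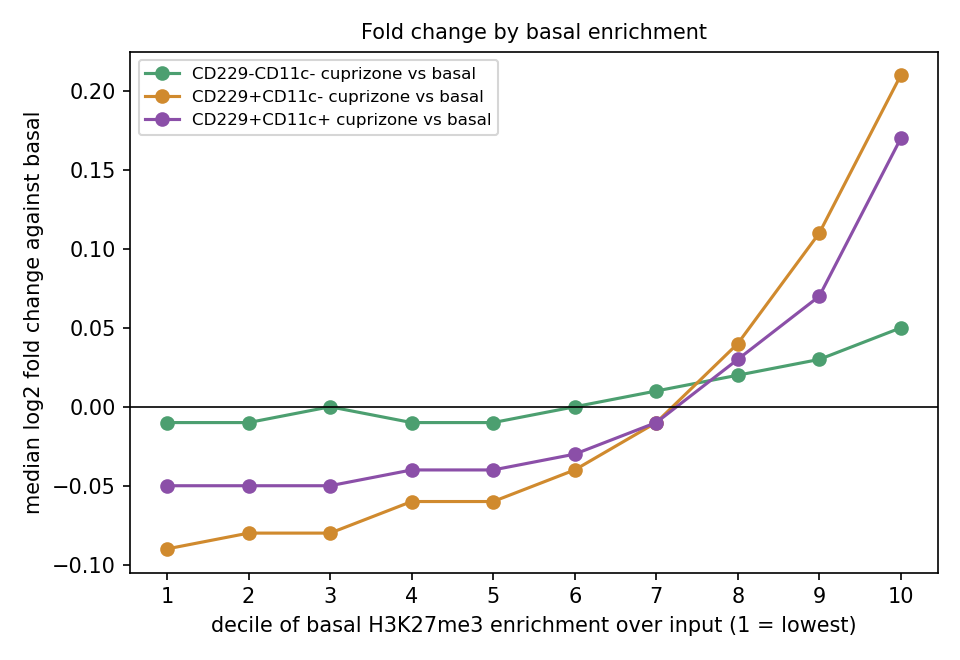
Median log2 fold change against basal microglia (y axis) of regions grouped into deciles by basal H3K27me3 enrichment over input (x axis), with 1 line per cuprizone subset. The median in the decile with the highest enrichment was 0.21 in CD229+CD11c-, 0.17 in CD229+CD11c+ and 0.05 in CD229-CD11c- microglia.

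The comparison of CD229-CD11c- cuprizone with basal microglia asked whether cuprizone cells without the CD229 and CD11c surface state differed in H3K27me3 at the basal regions. The labels give a gate on low CD44, CD45 and CD11b for basal microglia only, so an effect of the diet alone cannot be told apart from the sort. In every comparison the regions, apart from the added one, were called on basal libraries. A region marked only in cuprizone cells was therefore not counted. No region passed. The 5 regions with the smallest unadjusted p, which did not pass, lay near Zfhx4 (1.32), Hs3st3b1 (0.62), 5730435O14Rik (0.61), Dmrt1 (0.55) and Scrt1 (0.36), each with an adjusted p of 0.983. Lgals3, the galectin-3 gene, was at -0.48 (adjusted p = 0.983). The Hox clusters had fold changes between 0.08 and 0.11, none passing. Among the gene lists, 1 passed: the 68 regions of developmental transcription factors outside the Hox clusters had a median of 0.12 (adjusted p = 1.2e-11 by camera), with no region called and an adjusted p = 0.86 with an estimated correlation. Members of this list included Twist2 (0.68) and Tbx5 (0.49), which did not pass alone. The 19 regions of disease-associated microglia genes had a median of -0.06 (adjusted p = 0.25). edgeR called 0 regions, with 1103 at an unadjusted p under 0.05, and DESeq2 called 0 as well. The count was 30 without CD229-CD11c- replicate 3, 33 with a tag in the titles (PE150) as a covariate and 916 in the tagged libraries alone. That setting, with 2 libraries per group, was chosen after seeing the data; 1 library per group was untagged. What the tag marks is not given in the sources used here, and the labelled read length is 150 for tagged and untagged libraries alike among these 12. Of the 916 calls, 34.8% kept their sign in the untagged pair, against 47.2% of all regions.

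CD229+CD11c- cuprizone against basal microglia asked what changed where CD229 had appeared without CD11c. H3K27me3 rose at 64 of 68 regions of developmental regulators (29 with the 2-predictor offsets chosen after seeing the data) and 5 of 12 at Polycomb genes, and fell at 9 of 19 regions of disease-associated microglia genes. In all, 2506 regions rose and 913 fell, 3419 of 26326. The largest gain under the naming rule lay near Sema4b, a semaphorin gene (chromosome 7, 80169322 to 80191413, intergenic), from 97.4 ± 8.41 to 298 ± 31.8 CPM, a fold change of 1.61 ± 0.13 (adjusted p = 2.91e-07). An intronic region of Cux2, a homeobox gene (chromosome 5, 122042739 to 122049936), rose by 1.52 ± 0.13 (adjusted p = 9.64e-08), and a region near Lbr, the lamin B receptor gene, by 1.51 ± 0.21. The falls included -1.19 ± 0.13 at Oasl2, an interferon-induced gene, -1.10 ± 0.19 at Baz2a, and -1.0 ± 0.10 near Slc2a6, a sugar transporter gene. The Hox clusters rose together, by 0.69 ± 0.09 over Hoxa, 0.56 ± 0.06 over Hoxc, and 0.54 ± 0.07 over both Hoxb and Hoxd. Of the called gains, 56.8% had a TSS within 5 kb, against 15.3% of uncalled regions (odds ratio 7.28, 95% interval 6.67 to 7.95, Fisher's exact test), while 13.5% of the falls did (odds ratio 0.861, two-sided exact p = 0.133). Regions are not independent replicates in this test. Of the gains, 916 lay in the highest decile of basal enrichment and 38 in the lowest. Nearness to a TSS and basal enrichment were not separated.

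Among the 68 regions of developmental transcription factors outside the Hox clusters, 64 rose and none fell in CD229+CD11c- microglia (65 adjusted over the list alone). Their median was 0.56 (adjusted p = 1.6e-41, and adjusted p = 0.056 with an estimated correlation), or 0.25 with the 2-predictor offsets. Barhl2 rose by 0.83 ± 0.08, Six6 by 0.81 ± 0.07 and Foxc1 by 0.70 ± 0.07, homeobox and forkhead genes of neural, eye and body-wall development. Of 43 growth factor regions 15 rose and 6 fell (17 and 7 adjusted over the list alone; median 0.24, adjusted p = 0.0015, and adjusted p = 0.15 with an estimated correlation), with Gdnf at 1.11 ± 0.10 and Inhbb at 0.90 ± 0.12. Of 12 regions at Polycomb and H3K27 demethylase genes 5 rose (median 0.19, adjusted p = 0.0015, and adjusted p = 0.16 with an estimated correlation). An intronic region of Bmi1, which encodes a core subunit of Polycomb repressive complex 1 (chromosome 2, 18677307 to 18680319), went from 8.99 ± 1.73 to 25.6 ± 5.8 CPM, a rise of 1.51 ± 0.20 (adjusted p = 2.87e-05). Kdm6b, an H3K27 demethylase gene, rose by 0.95 ± 0.18. Lists of other cell types also passed, set against all other regions and not only those near a TSS. Of all regions with a TSS within 5 kb, 1424 rose, 123 fell and 3507 were not called. The lists were not tested against such regions alone, so gains of a list and gains common to regions near a TSS were not separated. The oligodendrocyte lineage list was higher in 5 of 9 regions (median 0.33, adjusted p = 0.00058, and adjusted p = 0.12 with an estimated correlation), with Nkx6-2 at 0.62 ± 0.10. The neuronal list was higher in 10 of 30 (median 0.21, adjusted p = 0.00058, and adjusted p = 0.16 with an estimated correlation), with Gad2 at 0.56 ± 0.07. The lymphocyte list was higher in 7 of 22 and lower in 1 (median 0.11, or -0.03 with total-count scaling; adjusted p = 0.038, and adjusted p = 0.16 with an estimated correlation), with Lef1 at 0.73 ± 0.07. The astrocyte list did not pass (6 higher and 2 lower of 18, median 0.15, adjusted p = 0.054), though Fgfr3 rose by 0.82 ± 0.10 and Sox9 by 0.64 ± 0.11, nor did the endothelial and mural list (6 higher and 1 lower of 16, median 0.21, adjusted p = 0.055).

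Of 19 regions at disease-associated microglia genes, 9 fell in CD229+CD11c- microglia (13 lower and 1 higher adjusted over the list alone; median -0.43, adjusted p = 3.5e-06, and adjusted p = 0.15 with an estimated correlation). Lgals3 fell by 1.45 on the log2 scale (SE 0.17, adjusted p = 4.74e-06), an intronic region of Etl4 by 1.2 (SE 0.16), Igf1, encoding an insulin-like growth factor, by 1.18 (SE 0.25), and Ch25h, encoding cholesterol 25-hydroxylase, by 1.01 (SE 0.17). Interferon response genes went both ways: of 9 regions 3 fell and 1 rose (median -0.22, adjusted p = 0.12), with Irf7 at -1.17 ± 0.20 and Gbp7 at 1.53 ± 0.19. Lipid handling genes did too, with 3 higher and 3 lower of 10 (median 0.03, mean -0.20, adjusted p = 0.83; median -0.11 with total-count scaling); Fabp5, a fatty-acid carrier gene, was at -1.0 ± 0.22. The other lists did not pass. Cytokine and NF-kappa-B genes were higher in 1 of 15 regions (median 0.01, or -0.13 with total-count scaling) and antigen presentation genes in 2 of 7 (0.03, or -0.13). Peripheral macrophage genes were lower in 1 of 8 (0.06, or -0.08). Neutrophil and dendritic cell genes were higher in 2 of 9 (median -0.11, mean 0.12) and cell cycle inhibitor genes in 2 of 5 (0.39). A region added to the authors' list at Bhlhe40, which encodes a transcription factor of activated myeloid cells (chromosome 6, 108660629 to 108666925), was chosen after its values were seen; it fell by 1.43 on the log2 scale (SE 0.16, adjusted p = 2.55e-06). With offsets that removed the trend of fold change with basal enrichment and tag density, chosen after seeing the data, 1185 regions were higher and 722 lower, and the growth factor, oligodendrocyte lineage, neuronal and lymphocyte lists no longer passed (medians 0.08, 0.11, 0.10 and 0.03). The growth factor, oligodendrocyte lineage and lymphocyte lists did not pass with regions up to 50 kb from the TSS either (0.07, 0.01 and 0.09). Total-count scaling, which moved the median of all regions by -0.14, gave 1578 higher and 3789 lower. The count was 2084 without basal replicate 4, 5828 with the PE150 tag as a covariate, 5532 in the tagged libraries alone and 143 at 2-fold or more.

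**Figure D2:**
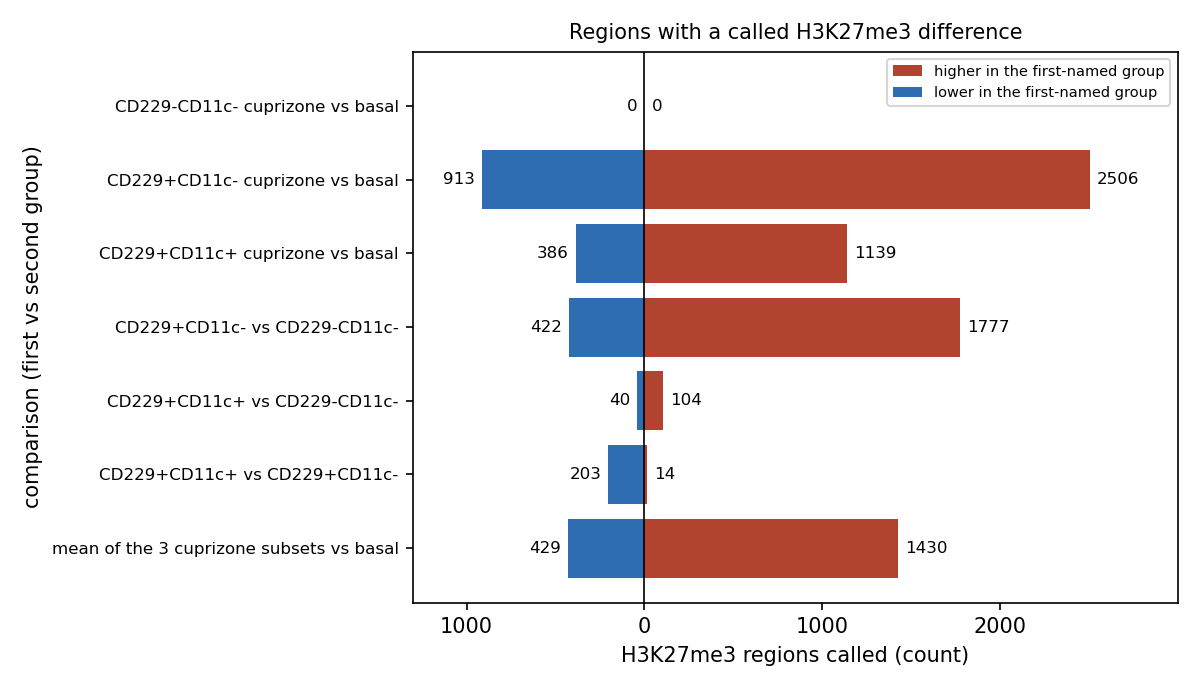
Number of H3K27me3 regions called higher and lower at an adjusted p under 0.05 (x axis, regions) in each of the 7 comparisons (y axis), with 1 bar per direction. CD229+CD11c- against basal microglia had 2506 higher and 913 lower regions, and CD229-CD11c- against basal microglia had 0.

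CD229+CD11c+ cuprizone against basal microglia asked what changed in the subset with both surface proteins. The mark fell at 7 of 19 regions of disease-associated microglia genes, most of all the named regions at Lgals3. It rose at 52 of 68 regions of developmental regulators and over the Hox clusters. In all, 1139 regions rose and 386 fell. Of all regions with a TSS within 5 kb, 693 rose, 85 fell and 4276 were not called. The intronic region of Lgals3 (chromosome 14, 47372854 to 47376837) went from 20.1 ± 1.72 to 2.89 ± 0.576 CPM, 6.85-fold lower (-2.78 ± 0.19, adjusted p = 4.82e-08). In an intron of Egr2, an immediate-early transcription factor gene (chromosome 10, 67537781 to 67541170), the level went from 16.5 ± 2.36 to 2.77 ± 0.369 CPM, a change of -2.56 ± 0.22 (adjusted p = 1.33e-06). The Bhlhe40 region was at -1.76 ± 0.16, an intron of Myof at -2.56 ± 0.27, and a region near Fam20c at -1.51 ± 0.16; these and Egr2 were chosen after their values were seen. Of 19 regions at disease-associated microglia genes 7 fell (8 lower and 1 higher adjusted over the list alone; median -0.35, adjusted p = 3.2e-09, and adjusted p = 0.15 with an estimated correlation). Besides Lgals3 these included Axl, a receptor for dying cells, at its promoter (-1.78 ± 0.29), Etl4 (-1.55 ± 0.16), Igf1 (-1.36 ± 0.25) and Ch25h (-1.13 ± 0.17). Further falls included -1.34 ± 0.13 at Inf2, -1.16 ± 0.16 at the promoter of Rai14, -1.09 ± 0.13 near Srarp, -1.01 ± 0.16 near Egr1, another immediate-early gene, -0.92 ± 0.15 near Flt1 and -0.90 ± 0.13 near Ptger4, a prostaglandin receptor gene.

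Gains in CD229+CD11c+ microglia included Sema4b (97.4 ± 8.41 to 226 ± 23.4 CPM, 1.21 ± 0.13, adjusted p = 3.72e-05), Adgrb1 (1.09 ± 0.22), Mmp15 (1.03 ± 0.11), Hmx1 (0.99 ± 0.20), Tafa5 (0.98 ± 0.18) and Ajuba (0.96 ± 0.13). Of the 68 regions at developmental transcription factors 52 rose and none fell (61 adjusted over the list alone; median 0.37, or 0.23 with the 2-predictor offsets; adjusted p = 3.2e-33, and adjusted p = 0.10 with an estimated correlation), among them Barhl2 (0.62 ± 0.08), Wt1 (0.60 ± 0.08) and Six6 (0.59 ± 0.07). The 4 Hox clusters rose by 0.31 to 0.35. Growth factor genes split into 12 higher and 3 lower of 43 (22 and 5 adjusted over the list alone; median 0.28, adjusted p = 0.0035, and adjusted p = 0.15 with an estimated correlation), with Gdnf at 0.86 ± 0.10, Bmp4 at 0.65 ± 0.10 and Pdgfa, a platelet-derived growth factor gene, at -1.36 ± 0.19. The neuronal list rose in 8 of 30 regions (median 0.20, or 0.11 with the 2-predictor offsets; adjusted p = 6.7e-06, and adjusted p = 0.15 with an estimated correlation), with Gad2 at 0.37 ± 0.07. No endothelial or mural region was called by edgeR, although that list passed (median 0.19, adjusted p = 0.023, and adjusted p = 0.15 with an estimated correlation). The oligodendrocyte lineage list did not pass (3 of 9 higher, median 0.19, adjusted p = 0.06). Nor did the lymphocyte (4 of 22 higher, median 0.04, or -0.04 with total-count scaling), astrocyte (2 of 18 higher, 0.11), Polycomb (1 of 12 higher, 0.15) and cell cycle inhibitor lists (2 of 5 higher, 0.11). Interferon response genes went both ways without the list passing (1 higher and 2 lower of 9, median -0.21), with Irf7 at -1.12 ± 0.19 and Gbp7 at 0.92 ± 0.19. Antigen presentation (1 of 7 lower, -0.14), cytokine and NF-kappa-B (0 of 15 called, -0.10) and lipid handling genes (1 higher and 2 lower of 10, -0.07) did not pass. Neither did peripheral macrophage (0 of 8 called, 0.03, or -0.03 with total-count scaling) and neutrophil and dendritic cell genes (1 of 9 higher, 0.00).

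**Figure D3:**
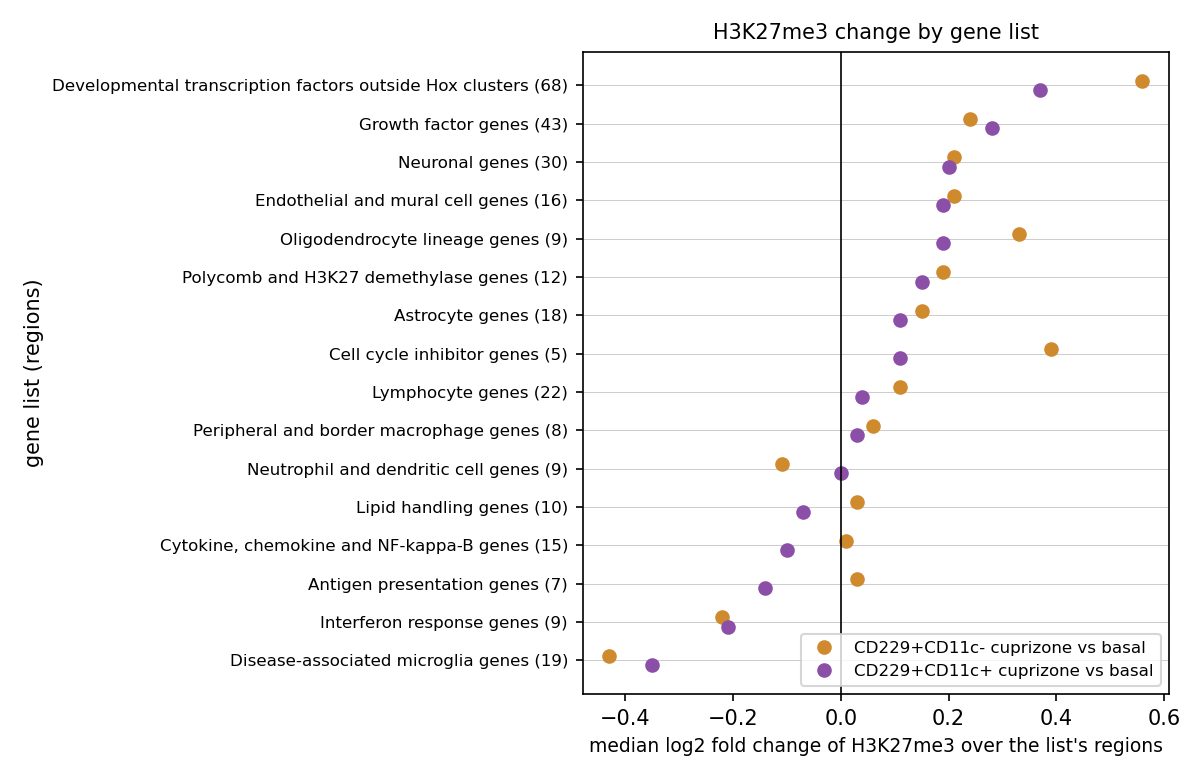
Median log2 fold change against basal microglia (x axis) of the regions within 10 kb of the TSS of each gene list (y axis, number of regions in brackets), with 1 point per list for CD229+CD11c- and for CD229+CD11c+ microglia. Developmental transcription factors had medians of 0.56 and 0.37 and disease-associated microglia genes -0.43 and -0.35; the medians of the lymphocyte and peripheral macrophage lists turned negative with total-count scaling in both subsets, and in CD229+CD11c- microglia so did those of the cytokine, antigen presentation and lipid handling lists.

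Many called regions were common to both CD229+ subsets. Of the regions called higher than basal, 982 were higher in both, against 108 if the calls were independent, and 214 were lower in both, against 13.4. Both subsets were set against the same basal libraries. Simulations without any effect gave a correlation of 0.489 between the fold changes across regions for that reason alone, against 0.729 observed. They left out the correlation between libraries of the same number (0.2, 0.08 and 0.33) and the trend with basal enrichment in both subsets. Either can raise the correlation, so the excess does not show a shared change at particular regions. Regions are not independent replicates. The single region called in opposite directions lay at the promoter of Pde4a, which encodes a cAMP phosphodiesterase (chromosome 9, 21163796 to 21167472), and was chosen after its values were seen. Its level was 14.7 ± 1.99 CPM in basal, 24.6 ± 5.04 CPM in CD229+CD11c- and 5.55 ± 0.881 CPM in CD229+CD11c+ microglia, fold changes of 0.75 ± 0.18 and -1.39 ± 0.21; the gain did not pass without CD229+CD11c- replicate 3 (adjusted p = 0.0522, the highest of 24 alternatives that went down to 4e-06). In CD229+CD11c+ against basal microglia 60.8% of gains had a TSS within 5 kb, against 17.2% of uncalled regions (odds ratio 7.46), and 22.0% of the falls did (odds ratio 1.36, two-sided exact p = 0.0174, not passing with a TSS within 1 kb). The 1525 calls became 869, 442 and 1012 without basal replicates 3, 4 and 5, 459 and 599 without CD229+CD11c+ replicates 1 and 2, and 2901 without CD229-CD11c- replicate 3. Total-count scaling gave 687 higher and 796 lower; the count was 4538 with the PE150 tag as a covariate, 4274 in the tagged libraries alone and 942 with offsets on basal enrichment chosen after seeing the data, which ended the growth factor and endothelial list calls (medians 0.12 and 0.17). At 2-fold or more there were 63 calls, of which 18 were higher and 45 lower.

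**Figure D4:**
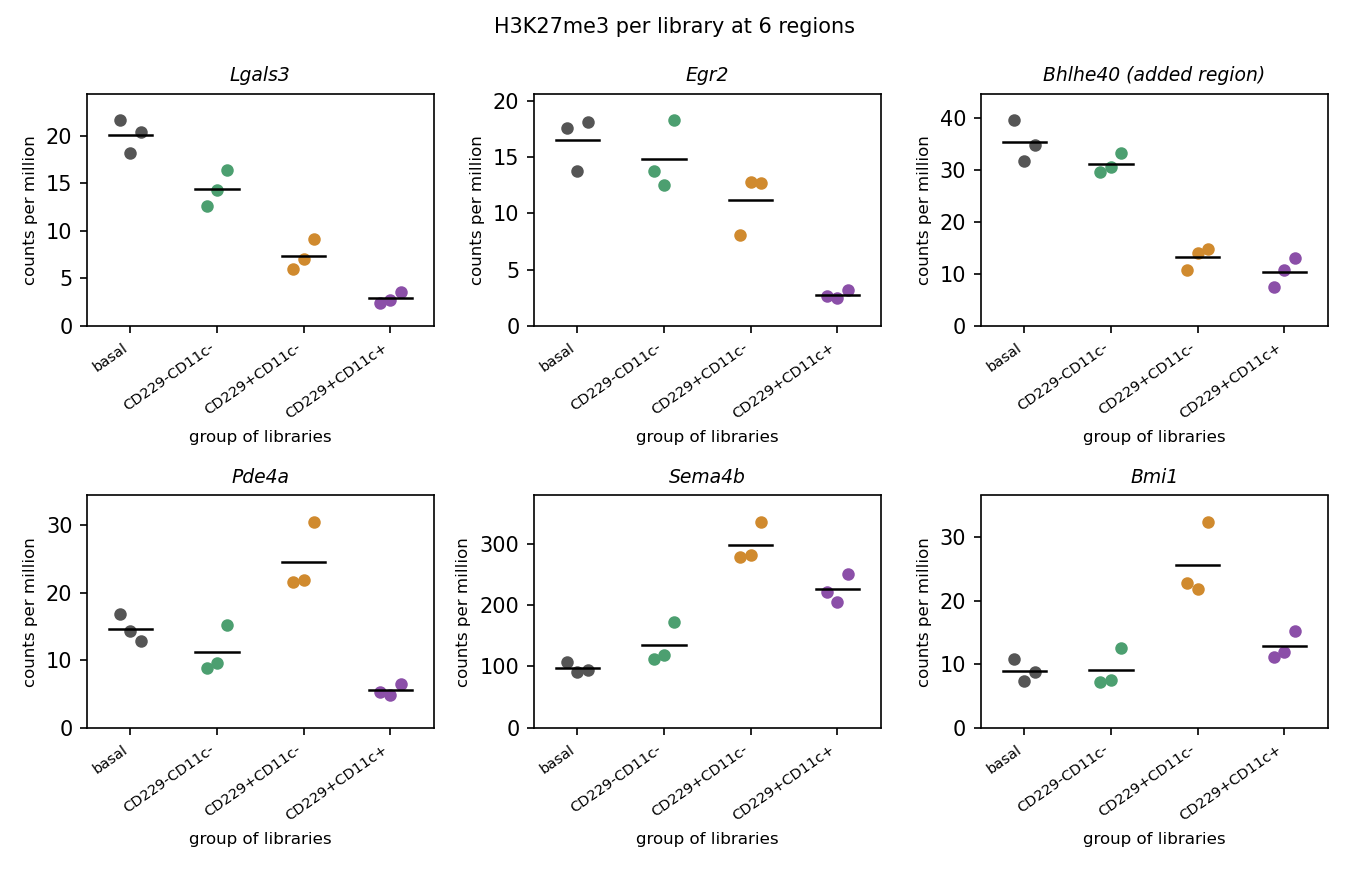
H3K27me3 level in CPM (y axis) of each library (points) and the mean of each group (line) at 6 regions, by group (x axis). Lgals3 was at 18.2 to 21.6 CPM in basal and 2.43 to 3.54 CPM in CD229+CD11c+ microglia, Egr2 at 13.8 to 18.1 and 2.48 to 3.18 CPM, and Pde4a at 21.5 to 30.4 CPM in CD229+CD11c- and 4.85 to 6.54 CPM in CD229+CD11c+ microglia.

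CD229+CD11c- against CD229-CD11c- microglia, both from cuprizone mice, asked what went with CD229 itself. CD229+CD11c- cells carried more of the mark at 55 of 68 regions of developmental regulators and 5 of 12 at Polycomb genes, and less at 7 of 19 of disease-associated microglia genes. Of 2199 regions called, 1777 were higher and 422 lower. Of all regions with a TSS within 5 kb, 1018 were higher, 74 lower and 3962 not called. A second region near Sema4b (chromosome 7, 80159841 to 80167167) was higher by 1.23 ± 0.11 (31.1 ± 4 to 73.3 ± 6.52 CPM, adjusted p = 2.56e-06), a region near Spag6 by 1.28 ± 0.23 and the Cux2 intron by 1.21 ± 0.12. Oasl2 was at -0.93 ± 0.13, Slc2a6 at -0.89 ± 0.10 and Baz2a at -0.84 ± 0.20. Of the 68 regions of developmental transcription factors 55 were higher (63 adjusted over the list alone; median 0.44, or 0.13 with the 2-predictor offsets; adjusted p = 1.2e-34, and adjusted p = 0.093 with an estimated correlation), with Six6 at 0.64 ± 0.07. Of the Polycomb regions 5 of 12 were higher (median 0.22, adjusted p = 0.00089, and adjusted p = 0.16 with an estimated correlation), with Bmi1 at 1.47 ± 0.21 and Kdm6b at 0.84 ± 0.18. The disease-associated list had 7 of 19 lower (12 adjusted over the list alone; median -0.45, adjusted p = 8e-06, and adjusted p = 0.14 with an estimated correlation), with Etl4 at -1.0 ± 0.16, Ch25h at -1.05 ± 0.17 and Lgals3 at -0.98 ± 0.18. Growth factor genes (10 higher and 1 lower of 43, median 0.15, adjusted p = 0.0053) and oligodendrocyte lineage genes (4 of 9 higher, 0.23, adjusted p = 0.0053) passed, each with an adjusted p = 0.14 with an estimated correlation. So did lymphocyte genes (5 of 22 higher, 0.10, or -0.02 with total-count scaling, adjusted p = 0.005) and astrocyte genes (5 higher and 2 lower of 18, 0.17, adjusted p = 0.036), with the same adjusted p = 0.14 with an estimated correlation. Neuronal genes passed too (7 of 30 higher, 0.12, adjusted p = 0.0038, and adjusted p = 0.20 with an estimated correlation). The promoter region of Pde4a was higher by 1.12 ± 0.19 and an intronic region of Ciita, which encodes the activator of MHC class II genes, by 0.68 ± 0.15, both chosen after their values were seen. With the replicate number as a block 4595 regions were called, 3155 higher and 1440 lower; the count was 4370 with the PE150 tag as a covariate, 3309 in the tagged libraries alone and 77 at 2-fold or more. Total-count scaling moved the median of all regions by -0.11 and gave 1059 higher and 1697 lower. The 2-predictor offsets chosen after seeing the data gave 471 higher and 288 lower. They ended the growth factor, oligodendrocyte lineage, lymphocyte, astrocyte and neuronal list calls (medians 0.06, 0.09, -0.01, 0.13 and 0.04), as did regions up to 50 kb from the TSS (0.02, -0.06, 0.06, 0.02 and 0.06).

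CD229+CD11c+ against CD229-CD11c- microglia compared the ends of the sort within cuprizone mice. Without a block 144 regions passed, 104 higher and 40 lower, and with the replicate number as a block 2025 did, 1554 higher and 471 lower. At 2-fold or more, without the block, 3 were higher and 22 lower. Lgals3 fell from 14.4 ± 1.87 to 2.89 ± 0.576 CPM (-2.30 ± 0.20, adjusted p = 3.21e-06). Etl4 was at -1.36 ± 0.16 and Ch25h at -1.18 ± 0.17, and under the naming rule Inf2 was at -1.26 ± 0.14, Rai14 at -1.03 ± 0.16 and Srarp at -0.82 ± 0.13. Among regions chosen after their values were seen were Myof (-2.76 ± 0.27), Egr2 (-2.41 ± 0.22), Bhlhe40 (-1.58 ± 0.16) and Fam20c (-1.15 ± 0.16). The disease-associated list had 5 of 19 lower (7 adjusted over the list alone; median -0.28, adjusted p = 1.8e-11, and adjusted p = 0.12 with an estimated correlation). Gains included Mmp15 (0.80 ± 0.11), Ajuba (0.80 ± 0.13), the second Sema4b region (0.75 ± 0.11), Rapgef3 (0.66 ± 0.10), Ptprf (0.64 ± 0.11) and Ube2m (0.62 ± 0.09). Developmental transcription factors had 8 of 68 regions higher (53 adjusted over the list alone; median 0.25, or 0.14 with the 2-predictor offsets; adjusted p = 6.4e-27), growth factor genes 1 higher and 2 lower of 43 (0.19, adjusted p = 0.0072) and neuronal genes 0 of 30 called (0.17, or 0.10 with these offsets; adjusted p = 8.9e-06). The endothelial list (0 of 16 called, 0.13, adjusted p = 0.021) and the interferon list (0 of 9 called, -0.13, adjusted p = 0.049, or 0.13 with the replicate block) also passed by camera, and each of these lists had an adjusted p = 0.12 with an estimated correlation. Six6 rose by 0.42 ± 0.07. Among gains 55.8% had a TSS within 5 kb and among falls 60.0%, against 19.0% of uncalled regions (odds ratios 5.38 and 6.4, two-sided exact p = 1.04e-16 and 1.27e-08). These p-values treat regions as independent, which they are not. The call count was 322 by DESeq2, 1638 with the PE150 tag as a covariate, 933 in the tagged libraries alone, and 60 higher against 50 lower with total-count scaling. The growth factor and endothelial lists did not pass with the 2-predictor offsets chosen after seeing the data (medians 0.10 and 0.07). The count was 68 and 271 without CD229-CD11c- replicates 2 and 3, and 44 and 59 without CD229+CD11c+ replicates 1 and 2.

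CD229+CD11c+ against CD229+CD11c- microglia asked what went with CD11c among CD229+ cells. The double-positive cells carried less of the mark at most called regions: 203 were lower and 14 higher. With the replicate number as a block 2199 regions were called, 486 higher and 1713 lower. Among the lower regions was an intron of Cbarp (39.6 ± 3.25 to 18.2 ± 1.4 CPM, -1.12 ± 0.15, adjusted p = 0.00187). Pde4a was at -2.13 ± 0.21 (adjusted p = 3.52e-05) and Egr2 at -1.99 ± 0.23 (adjusted p = 0.00027), both chosen after their values were seen; Bhlhe40, chosen likewise, was at -0.33 ± 0.17 and did not pass. Ciita was at -1.02 ± 0.15 (adjusted p = 0.00398, or 0.0533 without CD229+CD11c+ replicate 1, the highest of 23 alternatives that went down to 8.67e-13). Of the 203 lower regions 192 were called higher than basal in CD229+CD11c- microglia, against 2506 of all 26326 regions. Both calls rest on the same CD229+CD11c- libraries, so they are not independent. Of these regions 71 were higher than basal in both subsets and 120 were not called in CD229+CD11c+ microglia. Developmental transcription factors had 3 of 68 regions lower (29 adjusted over the list alone; median -0.18, adjusted p = 2.8e-11, or a median of 0.01 with the 2-predictor offsets chosen after seeing the data), and Polycomb genes 1 of 12 (4 adjusted over the list alone; -0.23, or -0.15 with these offsets; adjusted p = 0.00048), each with an adjusted p = 0.30 with an estimated correlation. Lymphocyte genes had 0 of 22 (4 adjusted over the list alone; -0.08, adjusted p = 0.025) and oligodendrocyte lineage genes 1 of 9 (-0.15, adjusted p = 0.011), also with an adjusted p = 0.30 with an estimated correlation. Antigen presentation genes had 1 of 7 lower (-0.20, adjusted p = 0.016, and adjusted p = 0.52 with an estimated correlation). With the 2-predictor offsets the lymphocyte, oligodendrocyte lineage and antigen presentation lists no longer passed (medians -0.02, -0.03 and -0.16). The disease-associated list did not pass (1 of 19 lower, median -0.09, adjusted p = 0.35), and neither did the growth factor list (0 higher and 3 lower of 43, -0.01, or 0.06 with total-count scaling). Of the lower regions 61.1% had a TSS within 5 kb, against 18.9% of uncalled regions (odds ratio 6.74). The count was 668 by DESeq2 (26 higher, 642 lower), 28 with total-count scaling (3 higher, 25 lower), 1920 with the PE150 tag as a covariate, 1397 in the tagged libraries alone, and 7 at 2-fold or more. With the offsets chosen after seeing the data it was 34 on enrichment alone (1 higher, 33 lower) and 45 on 2 predictors (20 higher, 25 lower). Without CD229+CD11c+ replicates 1 and 2 it was 10 and 9, without CD229+CD11c- replicates 1, 2 and 3 it was 64, 39 and 14, and without CD229-CD11c- replicate 3 it was 830.

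The mean of the 3 cuprizone subsets against basal microglia asked how the subsets differed from basal cells on average, not what all 3 shared. Of 1859 regions called, 1430 were higher and 429 lower. Of all regions with a TSS within 5 kb, 869 were higher, 70 lower and 4115 not called. Sema4b (1.10 ± 0.11), Mmp15 (0.88 ± 0.10) and Tbx5, a T-box gene of heart and limb development (0.80 ± 0.11), were the largest gains under the rule, and Setbp1 (-0.50 ± 0.09) and Dzank1 (-0.47 ± 0.08) fell. Lgals3 fell by 1.57 on the log2 scale (SE 0.13, adjusted p = 1.67e-06), Axl by 1.16 (SE 0.21) and Etl4 by 0.98 (SE 0.12). Developmental transcription factors rose in 57 of 68 regions (65 adjusted over the list alone; median 0.34, or 0.19 with the 2-predictor offsets; adjusted p = 3.8e-39, and adjusted p = 0.066 with an estimated correlation), and disease-associated genes fell in 7 of 19 (10 lower and 1 higher adjusted over the list alone; median -0.24, adjusted p = 1.9e-07, and adjusted p = 0.16 with an estimated correlation). Other lists passed upward: neuronal (7 of 30 higher, median 0.17, adjusted p = 9e-05), oligodendrocyte lineage (3 of 9, 0.21, adjusted p = 0.0025), growth factor (14 higher and 4 lower of 43, 0.19, adjusted p = 0.0025), Polycomb (5 of 12, 0.16, adjusted p = 0.046) and endothelial genes (1 of 16, 0.15, adjusted p = 0.046). With an estimated correlation none of these passed (adjusted p = 0.16 to 0.39), nor with the 2-predictor offsets (medians 0.06, 0.08, 0.07, 0.11 and 0.12). Total-count scaling gave 826 higher and 1303 lower; the count was 4548 with the PE150 tag as a covariate, 4937 in the tagged libraries alone, 928 and 959 with the offsets on 1 and 2 predictors and 24 at 2-fold or more. It was 1115, 481 and 1108 without basal replicates 3, 4 and 5, and 3681 without CD229-CD11c- replicate 3.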

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

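The tests of explanations in this part, with the refits of other splits of the libraries, were chosen only after the results were seen. Some fits they used had been planned as alternatives: total-count scaling, the PE150 covariate and each library left out in turn. The comparisons between subsets had been planned too. The cuprizone subsets differed from each other in tests of the difference itself: 2199 regions passed between CD229+CD11c- and CD229-CD11c-, 144 between CD229+CD11c+ and CD229-CD11c-, and 217 between CD229+CD11c+ and CD229+CD11c- microglia. Groups of 3 libraries were not tested for a sample far from the others. The 3 libraries against 3 make 10 splits, too few for a share under 0.05; in these comparisons, and in CD229+CD11c- (3419 regions) and CD229+CD11c+ microglia (1525) against basal, the highest other split gave 0 regions and 1 split, the real one, gave as many. In CD229-CD11c- against basal microglia all 10 splits gave at least the real count of 0, and the highest other gave 1440. That split set basal replicates 3 and 4 and CD229-CD11c- replicate 3 against the other 3 libraries, which points to a structure of the samples. For the mean of the 3 subsets against basal microglia 2 of 100 splits gave at least the real 1859 regions, and the highest other, 2797, put the same 3 libraries on the basal side; these splits mix libraries of subsets that themselves differed, so they do not settle whether chance is excluded.

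Some named regions stood out because their fold changes against basal microglia had opposite signs in the subsets compared and the difference itself passed. The signs need not mean opposite changes. No fold of CD229-CD11c- against basal microglia passed, and that of Ciita, for example, was -0.08. Only Pde4a was called in opposite directions against basal microglia, by the CD229+ subsets. CD229+CD11c- against CD229-CD11c- microglia gave Myof -1.74, Ch25h -1.05, Pianp -0.50 and Fgfbp1 -0.47 (log2), and Neurl1a 1.16, Pde4a 1.12, Ptprf 1.06, Ptcd2 0.97, Ciita 0.68, Pdgfra 0.51 and Slc4a4 0.49. Pianp did not pass without CD229-CD11c- replicates 1 and 3 (-0.51 and -0.39) or CD229+CD11c- replicates 1 and 2 (-0.44 and -0.43). It did not pass with only these groups in the model either (-0.49). With the 2-predictor offsets Fgfbp1 (-0.37), Pdgfra (0.15) and Slc4a4 (0.30) did not pass. CD229+CD11c+ against CD229-CD11c- microglia gave Myof -2.76, Ch25h -1.18, Pianp -0.68, Plxnc1 -0.68, Ptprf 0.64 and Ptcd2 0.62. Without CD229+CD11c+ replicates 1 and 2, Pianp (-0.67 and -0.59), Plxnc1 (-0.67 and -0.62) and Ptcd2 (0.67 and 0.60) did not pass, nor did Ptcd2 without CD229+CD11c+ replicate 3 (0.59) and CD229-CD11c- replicates 1 and 2 (0.63 and 0.53). Pianp, Plxnc1 and Ptcd2 did not pass with only these groups in the model, and Ptcd2 not with total-count scaling (0.57).

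CD229+CD11c+ against CD229+CD11c- microglia gave Pde4a -2.13, Ciita -1.02, Pparg -0.57, Tgfb2 -0.50 and Fgfbp1 0.45 on the same ground. Ciita did not pass without CD229+CD11c+ replicate 1 (-0.91). Without CD229+CD11c+ replicates 1 and 2 Pparg (-0.52 and -0.55) and Tgfb2 (-0.50 and -0.43) did not pass, nor without CD229+CD11c- replicate 3 (-0.46 and -0.43). Pparg did not pass without CD229+CD11c- replicates 1 and 2 either (-0.61 and -0.63). Fgfbp1 passed without basal replicate 3 and without CD229-CD11c- replicate 3, and in none of the other 10 fits with 1 library left out (0.40 to 0.51). In total-count scaling and with the 2-predictor offsets Pparg (-0.50 and -0.34), Tgfb2 (-0.44 and -0.30) and Fgfbp1 (0.52 and 0.39) did not pass.

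The gains of CD229+CD11c- microglia follow basal enrichment, as a library with more signal over background would show. For the developmental transcription factors the 2-predictor offsets took the median from 0.56 (SD 0.21) to 0.25 (SD 0.22). Of their 68 regions 29 were then called higher and 0 lower, so the fitted trend did not take away the whole gain. Of all 2506 gains 1044 stayed called, and their median went from 0.48 (SD 0.23) to 0.27 (SD 0.29). In either set the trend and a change in the cells cannot be told apart. Each SD is a spread over regions, not an error of the median. With total-count scaling the median of the developmental list was 0.42 (SD 0.21). That scaling shifted the regions together (median shift -0.14) and also used only tags in the regions, so it cannot decide on TMM. The 203 regions higher in CD229+CD11c- than in CD229+CD11c+ microglia are consistent with the trend, since 25 stayed called while the median went from -0.41 (SD 0.25) to -0.20 (SD 0.30) and the median SE stayed at 0.08, so these calls ended because the folds shrank; Pde4a stayed at -1.90 (adjusted p = 2.3e-06). A difference that goes with the surface states stays open as untested.

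The losses at disease-associated microglia genes in CD229+CD11c+ microglia had a median of -1.55 over the 7 called regions. The 7 regions were picked by their fall, so setting that median against whole lists cannot decide whether cells of another type were the cause. Of the disease-associated list 7 of 19 regions were called lower. Of the peripheral macrophage, lymphocyte, and neutrophil and dendritic cell lists 0 of 39 were. Those lists had medians of 0.03 (SD 0.17), 0.04 (SD 0.25) and 0.00 (SD 0.36) and lowest members of -0.14, -0.40 and -0.64. Of their genes, 2 of 25, 2 of 32 and 3 of 24 are also in another list. The labels give a gate on low CD44, CD45 and CD11b for basal microglia only. For the list as a whole, whose median of -0.35 lies within 1 SD of the 0.00, cells of another type and a change in the mark cannot be told apart. A single library is argued against for 5 of the 7, which stayed called in each of 12 fits with 1 library left out. Only the fits without a basal or a CD229+CD11c+ library bear on this. The other fits left the libraries compared unchanged. Apoe ended without basal replicate 4 (-1.66), CD229-CD11c- replicate 3 (-1.70, the same fold as with all libraries) and CD229+CD11c+ replicate 1 (-1.27). Dkk2 ended without basal replicates 3 and 4 (both -0.52) and CD229+CD11c+ replicates 1 and 2 (-0.55 and -0.44). A change in the input background of these regions and a change in the mark cannot be told apart, because the table of counts holds 0 input columns.

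The absence of calls between CD229-CD11c- and basal microglia might rest on CD229-CD11c- replicate 3, and this cannot be told apart from a lack of change. Without it 30 regions were called. Of the 916 calls in the tagged libraries, 34.8% kept their sign in the untagged pair, which includes that library, against 47.2% of all regions. The same library is in the untagged pairs of CD229+CD11c- and CD229+CD11c+ against CD229-CD11c- microglia. There 93% and 92.8% of such calls kept their sign (65.4% and 59.2% of all regions). For these subsets against basal microglia 91.4% and 90.3% did, so the low share was confined to 1 comparison. An additive difference between tagged and untagged libraries cannot be told apart from a lack of change either: the tag as a covariate gave 33 calls in the same libraries, what the tag marks is not given in the sources used here, and 1 library per group is untagged. Whether CD229-CD11c- cells differ from basal cells stays open.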

How the results depend on the processing

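The loess offsets, the tagged libraries alone and the lists with the PE150 covariate or gene spans were chosen after seeing the data. Scaling to genome-wide totals, and the share of each library's tags in the regions, were not run, because no genome-wide totals of the 12 libraries were given in the sources used here. The filter on low counts removed 0 regions, so leaving it out tested nothing. With DESeq2 size factors, at least 30 counts or a non-robust dispersion, the 7 counts of calls stayed within 1.5 times their value. Over all alternatives, 6944 values of named regions kept their side of the threshold, 322 of them with the filter left out. Another 513 no longer passed, 198 newly passed and 2 reversed. A change of sign counted as reversed only where either fit passed, so the 6944 can include changes of sign among values that did not pass. The gene list tests, counted by the same rule on the test's direction, gave 703, 101, 13 and 1 in the same order. In simulated data with the observed depth, spread and group size, 61% of 1.5-fold and 96% of 2-fold changes were recovered, so smaller changes can be missed; depth was not varied alone. Where no cause is named, the cause was not tested.

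Requiring at least 2-fold, which by construction removes calls, left 143 regions in CD229+CD11c- and 63 in CD229+CD11c+ against basal microglia, 77 in CD229+CD11c- and 25 in CD229+CD11c+ against CD229-CD11c-, 7 in CD229+CD11c+ against CD229+CD11c- microglia, and 24 for the mean of the subsets. Total-count scaling gave 5367 in CD229+CD11c- against basal and 28 in CD229+CD11c+ against CD229+CD11c- microglia, in place of 3419 and 217. DESeq2 gave 322 in CD229+CD11c+ against CD229-CD11c- and 668 in CD229+CD11c+ against CD229+CD11c- microglia, in place of 144 and 217. With only the groups compared, the counts were 2977 in CD229+CD11c+ against basal, 50 in CD229+CD11c+ against CD229-CD11c- and 631 in CD229+CD11c+ against CD229+CD11c- microglia.

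With the PE150 covariate the counts against basal microglia were 33 for CD229-CD11c-, 5828 for CD229+CD11c-, 4538 for CD229+CD11c+ and 4548 for the mean, and with the barcode-series block 19, 5637, 4312 and 4352. Between subsets the covariate gave 4370 in CD229+CD11c- and 1638 in CD229+CD11c+ against CD229-CD11c-, and 1920 in CD229+CD11c+ against CD229+CD11c- microglia; the replicate block gave 4595, 2025 and 2199. The tagged libraries alone gave 916, 5532, 4274 and 4937 against basal microglia, in the order above, and 3309, 933 and 1397 between subsets.

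Loess offsets on basal enrichment gave 942 in CD229+CD11c+ against basal, 1345 in CD229+CD11c- against CD229-CD11c-, 34 in CD229+CD11c+ against CD229+CD11c- microglia and 928 for the mean. With tag density added they gave 1907 in CD229+CD11c- against basal, 759 in CD229+CD11c- against CD229-CD11c-, 45 in CD229+CD11c+ against CD229+CD11c- microglia and 959 for the mean. These 2-predictor offsets also reversed the developmental transcription factor list in CD229+CD11c+ against CD229+CD11c- microglia (0.01, from -0.18), and the regions of Sox17 (-0.10, from 0.30) and Esam (-0.15, from 0.31) in CD229+CD11c- against basal microglia.

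With 1 library left out, the counts against basal microglia ran from 0 to 30 for CD229-CD11c-, 2084 to 4589 for CD229+CD11c-, 442 to 2901 for CD229+CD11c+ and 481 to 3681 for the mean. Between subsets they ran from 1532 to 2576 in CD229+CD11c- and 44 to 271 in CD229+CD11c+ against CD229-CD11c-, and from 9 to 830 in CD229+CD11c+ against CD229+CD11c- microglia. The highest count came without CD229-CD11c- replicate 3 in all 7 comparisons; the lowest came without basal replicate 4 for CD229+CD11c-, CD229+CD11c+ and the mean, without CD229+CD11c- replicate 2 (1532), and without CD229+CD11c+ replicates 1 (44) and 2 (9).

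Of the gene list tests 39 passed, 28 up and 11 down. With an estimated correlation 0 passed, with regions within 50 kb 25, with loess offsets on enrichment 23 and with the 2-predictor offsets 19. Medians of lists that passed changed sign, with no change of the test's direction, for lymphocyte genes in CD229+CD11c- microglia with total counts (0.11 to -0.03 against basal, 0.10 to -0.02 against CD229-CD11c-). Against CD229-CD11c- they also did with the 2-predictor offsets (-0.01), as did oligodendrocyte lineage genes with regions within 50 kb (0.23 to -0.06). With total counts, 1 region per gene and the PE150 covariate 40, 40 and 37 passed, and with the replicate block 18 of those between subsets. The median length of basal regions, 6386 bp, was 11783 bp among those at or above the median peak score.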

Other observations

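The hypothesis in the last paragraph, its test and the gene lists by gene span were chosen only after the results were seen. By overlap with the gene span, 13 regions lay at interferon response genes. In CD229+CD11c- against basal microglia 5 of 13 were lower and none higher (median -0.42, adjusted p = 3e-04, and adjusted p = 0.13 with an estimated correlation), and in CD229+CD11c+ microglia 5 were lower and none higher (median -0.29, adjusted p = 0.001, and adjusted p = 0.17 with an estimated correlation). The list by distance to the TSS went both ways and did not pass in either subset. By gene span, neutrophil and dendritic cell genes also passed, upward, in CD229+CD11c- (6 of 14 higher, median 0.28, adjusted p = 0.00056) and CD229+CD11c+ microglia (4 of 14, 0.14, adjusted p = 0.027). In CD229+CD11c+ microglia so did Polycomb genes (1 of 10 higher, 0.23, adjusted p = 0.038) and lymphocyte genes (7 of 64 higher, 0.07, adjusted p = 0.032), and, downward, antigen presentation genes (2 of 7 lower, -0.17, adjusted p = 0.027). None of these passed with an estimated correlation (adjusted p = 0.13 to 0.39). List calls were also lost by gene span: lymphocyte genes in CD229+CD11c- (adjusted p = 0.13) and endothelial genes in CD229+CD11c+ against basal microglia (adjusted p = 0.10). Against CD229-CD11c- microglia, lymphocyte and astrocyte genes were lost in CD229+CD11c- (adjusted p = 0.15 and 0.75) and endothelial genes in CD229+CD11c+ (adjusted p = 0.33). Interferon, and neutrophil and dendritic cell genes newly passed in CD229+CD11c- against CD229-CD11c- microglia, but not with an estimated correlation (adjusted p = 0.083 and 0.19). Antigen presentation, lipid handling, Polycomb and lymphocyte genes did in CD229+CD11c+, but not with an estimated correlation (adjusted p = 0.34, 0.28, 0.4 and 0.28). Between the CD229+ subsets, cytokine, lipid handling, and neutrophil and dendritic cell genes newly passed, while antigen presentation and lymphocyte genes were lost. With an estimated correlation those 3 new calls did not pass (adjusted p = 0.47, 0.35 and 0.35). For the mean of the subsets the interferon, and neutrophil and dendritic cell lists newly passed and the endothelial list was lost. In CD229-CD11c- against basal microglia the neuronal list newly passed. These new calls also ended with an estimated correlation (adjusted p = 0.16 for each list of the mean and 0.76 for the neuronal list). The broad region around Bhlhe40 (109 kb, chromosome 6, 108632597 to 108741110) fell with the region the authors added inside it. It was at -0.42 ± 0.09 in CD229+CD11c- (adjusted p = 0.0021) and -0.46 ± 0.09 in CD229+CD11c+ (adjusted p = 0.0039) against basal microglia, and at -0.07 ± 0.09 in CD229-CD11c- microglia, where it did not pass.

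The authors' deposited table, at an adjusted p under 0.05, held 0 regions for CD229-CD11c- against basal microglia, 3563 for CD229+CD11c- (2742 higher, 821 lower) and 2324 for CD229+CD11c+ (1720 higher, 604 lower). Of those in the authors' deposited table, 3201 and 1504 were also called here in the same direction. Between subsets, the authors' deposited table held 1579 regions for CD229+CD11c- and 132 for CD229+CD11c+ against CD229-CD11c-, and 699 for CD229+CD11c+ against CD229+CD11c- microglia (31 higher, 668 lower), of which 1555, 103 and 191 were also called here. In 2 comparisons the adjusted p of the authors' deposited table was 1 for a large share of regions: 14802 in CD229+CD11c+ against CD229-CD11c- and 16333 in CD229+CD11c+ against CD229+CD11c- microglia. Their median level in the authors' normalized signal was 114 and 121, against 426 and 480 for the other regions, and 30 and 26 of them were called here. The highest mean level among them was 264.8 and 301.7. This adjusted p therefore went with low levels and need not mean a lack of difference. In the authors' deposited table, Lgals3 had -2.31 and Egr2 -2.42 in CD229+CD11c+ against CD229-CD11c- microglia, each with an adjusted p of 1, and Pde4a -2.13 in CD229+CD11c+ against CD229+CD11c- microglia, also with an adjusted p of 1. DESeq2 run here gave no adjusted p for 6125 and 17354 regions of these comparisons.

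In a principal component analysis of log2 CPM, the first component held 30.4% and the second 21.8% of the variance. CD229-CD11c- replicate 3 lay at -33.6 and 10.3, and CD229-CD11c- replicates 1 and 2 lay at 6.4 and -19.6, and at 2.1 and -21.1. Basal replicates 3, 4 and 5 lay at -27.2, -23.7 and -11.9 on the first component.

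A candidate explanation for folds of CD229-CD11c- microglia that did not pass is that these cells share part of the CD229+CD11c- change. Across regions the covariance of the fold changes of both subsets against basal microglia was 0.0218. In 20 simulations with no effect and the same shared basal libraries it was 0.0127, an excess of 0.00909. The simulations left out the correlation between libraries of the same replicate number (0.28, 0.13 and 0.46), which can add covariance without an effect. The correlation of these fold changes, in contrast, was 0.477 against 0.487 in the simulations. For CD229-CD11c- with CD229+CD11c+ microglia the covariance was 0.0244 against 0.0127 in the simulations. The correlation of that pair was 0.609 against 0.49. The hypothesis and its absence cannot be told apart with these values. The covariance was below 3 times its mean in the simulations, the limit that was set, and regions are not independent replicates.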
